A study of Oryza sativa with 17 samples.

How the data were processed

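The data are scans of Agilent one-colour rice arrays hybridised with Cy3-labelled RNA from leaves of 3 cultivars under 2 treatments, in 6 groups and 17 arrays. Per the labels, leaves came from different plants of each cultivar and treatment, RNA was isolated with TRIzol and columns, and labelling used a low-input one-colour kit. The design text names the reproductive stage, and the labels give 35 days after sowing. Groups and replicate numbers come from the labels.

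The scanner files hold intensity values per spot, which the authors extracted with Agilent Feature Extraction (version 11.0 per the submitters' processing notes, 11.5.1.1 per the file headers), using the protocol GE1_1105_Oct12 and a design that the headers tie to rice build IRGSP5. Per the file headers the processed signal is background-subtracted. Each array has 62976 features, of which 61657 are rice spots for 52901 probes, 8756 of them spotted as 2 copies. The deposited value table holds log2 values whose scale and centring the labels leave open. Set against the scanner signal, its columns rose with quantile-normalized log2 signal centred on each locus's median over the arrays (lowest r 1.000 across loci), so the direction is that of signal. It was used as an alternative.

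Spots with an outlier flag (138 over all arrays) and control spots were left out, and spots of 1 probe were averaged. Signal was taken as log2 minus each array's 75th percentile. A locus was tested where it was well above background, by the scanner software's flag, on every array of at least 1 group, which kept 34341 loci and left out 18560. Limma 3.58.1 in R 4.3.3 fitted all arrays in 6 groups with no covariate, and lmFit and eBayes gave moderated tests with Benjamini-Hochberg adjustment over loci, with an adjusted p of 0.05 as the threshold. The 12 contrasts were drought against well-watered in each cultivar, the differences between these responses, and the differences between cultivars under each treatment. Log2 changes are given with their standard error. Where a locus was not well above background on any array of 1 group, the fold is a lower bound. It sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the locus's own signal and the lowest signal among probes well above background. The number of arrays limits the precision. The p-values measure the spread between arrays of 1 experiment, each from a different plant, so plant and array are not separated in it.

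The array names each probe by a rice locus identifier of the MSU annotation, with exactly 1 probe per locus, so that alternatives on several probes per gene did not apply. The reference table of gene names, from assembly ASM3414082v1, matched 1 of 52901 identifiers. The 27 gene lists, word patterns on gene descriptions, and the 9 anchor genes fixed before the data were examined could therefore not be matched to probes and were not tested. Loci are given by identifier alone, at most 2 per direction and comparison. Chromosome number and order along it were read from the identifier. The rule for naming loci, fixed before the data were examined, took for each cultivar the loci with the largest rise and fall that passed the test with no overlap between treatments, and the largest differences in each direction for differences between responses and between well-watered cultivars. It asked for a gene description as well, a condition that could not be applied, so that only the first 2 loci per direction are given where the rule allowed more. It also named loci in runs nearer Way Rarem, which are not named because the longest run (4 loci) was no longer than the median of permuted labels (4).

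The position of the bred line was computed as fixed beforehand, at loci where the parents differed with adjusted p under 0.05 and by at least 1 log2 unit in the same direction under both treatments, as (bred line minus Vandana) over (Way Rarem minus Vandana), averaged over treatments. Circular shifts cannot change the length of a run, so runs and neighbouring pairs were tested with 10000 random permutations of the labels. Shifts were used for the highest share on a chromosome (40.6%, permutation p = 0.417).

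Of 4 slides, each scanned together, no slide held both treatments of 1 cultivar. Slide as a fixed block allowed 6 of the 12 contrasts, through groups that lie on more than 1 slide, and slide as a random block allowed all (consensus correlation -0.05). Alternatives fixed beforehand were other normalizations, filters, priors and array weights, blocks for slide and replicate number, the deposited value table, a fold minimum and leaving out each array. Normexp background correction was planned on the mean spot signal, a column that these scanner files lack, so it could not be run as planned. Alternatives chosen after seeing the data were normexp on the median spot signal, scaling to the 6 brightest E1A probes, leaving out both Way Rarem number 1 arrays, a stricter filter, fits within a slide and a larger parental difference.

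The fit was tested on simulated data built from the real means and residual spreads of 34341 loci. With 200 changed loci, it recovered none of the 100 changes of 1 log2 unit and 38% of those of 2 units for the drought response in Vandana, and 30% of the latter in the bred line. With 4000 changed loci, a size added after the first run, it recovered 22.9% and 70.2% in Vandana and 15.2% and 61.6% in the bred line. In a simulation of the position of the bred line, every selected locus in the simulated Way Rarem segments was placed nearer Way Rarem and no other was. All simulated parental differences exceeded 2 log2 units and loci varied independently, so this result does not cover smaller parental differences.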

Results

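Leaf transcripts of 3 rice cultivars were compared under continuous watering and under drought. The cultivars are Vandana, Way Rarem and a line called the bred line below. The bred line is known from the literature as bred from a cross of Vandana and Way Rarem. Per the literature it carries a Way Rarem segment on chromosome 12 associated with yield under drought. In the figures it keeps its label, which is a number and a letter. Well-watered soil was held at field capacity, and the drought soil dried down from 75% of field capacity. Leaves were sampled 35 days after sowing, from different plants for each array. The series holds 17 one-colour arrays, with 3 arrays in each of 5 groups and 2 in the well-watered group of the bred line. Each array measured 52901 rice loci with 1 probe per locus, and 34341 loci were well above background on every array of at least 1 group and were tested.

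The arrays differed in brightness, which sets how many loci each could measure. The share of probes well above background ran from 46.1% on Vandana drought replicate 1 to 96.9% on Way Rarem well-watered replicate 1, and the 75th percentile of the signal from 31.9 to 549 intensity units on those arrays. No rice spot was saturated. Relative to the E1A control transcripts added during labelling, the 75th percentile of rice signal differed between drought and well-watered leaves by -1.52 log2 units in the bred line, -0.38 in Vandana and -0.84 in Way Rarem, a mean of -0.91 (exact permutation test within cultivars, two-sided p = 0.0423). In the bred line, drought replicates 1 to 3 stood at -6.63, -4.45 and -6.57 on this measure and the well-watered arrays at -4.33 and -4.39, so replicate 2 hardly shared the drop. Values below are relative to the 75th percentile of each array, so they describe changes relative to the other transcripts of the leaf. Within a group, arrays correlated at 0.85 or more across loci, and no array repeated another. Drought replicate 2 of the bred line correlated best with a well-watered array of its cultivar (0.95, against 0.90 at best in its own group), and Way Rarem drought replicate 2 correlated best with that array (0.91). This Way Rarem array also correlated better with a well-watered array of its cultivar than with its own group (0.898, against 0.890 at best). Drought and well-watered arrays of a cultivar never shared a slide.

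In the bred line, 4328 loci were higher and 4319 lower under drought (limma, adjusted p under 0.05; 3 against 2 arrays). Of these, 4237 rose and 4048 fell by at least 1 log2 unit. The largest rise was at LOC_Os08g01370, by 8.44 (SE 0.94, adjusted p = 3.92e-04), and this locus also rose by 5.19 in Vandana and 7.23 in Way Rarem. LOC_Os01g68290 rose by 8.10 (SE 1.60, adjusted p = 0.00638), although only 1 of the 2 well-watered arrays measured it above background. LOC_Os06g05050 fell by 6.52 (SE 1.25, adjusted p = 0.00565) and was above background on 1 of 3 drought arrays. The sizes of this rise and this fall are not measured. LOC_Os01g74160 was not well above background on any drought array and was at least 43.2-fold lower (adjusted p = 0.00165). The counts depended on single arrays. Without well-watered replicate 1 or 3, 90 or 579 loci were higher and 123 or 586 lower, where the remaining array is assumed to vary like the other groups. Without drought replicate 1 or 3, 955 or 892 were higher and 1073 or 987 lower, and without drought replicate 2, 8210 and 7383. With slide as a fixed block, 87 were higher and 112 lower. This fit joins the slides of the 2 treatments through Way Rarem drought replicate 1 alone.

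In Vandana, 3468 loci were higher and 4075 lower under drought (3 against 3 arrays), 3263 and 3444 of them by at least 1 log2 unit. LOC_Os05g28740 rose the most, by 7.97 (SE 0.62, adjusted p = 3.53e-05), from -2.19 ± 0.63 to 5.78 ± 1.25 (mean ± SD, n = 3). It rose by 6.86 in the bred line and 7.40 in Way Rarem. LOC_Os03g07180 rose by 6.95 (SE 0.98, adjusted p = 0.00115) and by 7.47 and 7.0 in the bred line and Way Rarem. Only 1 of 3 well-watered Vandana arrays measured it above background, so the size of its rise in Vandana is not measured. LOC_Os03g09250 was not well above background on any drought array of Vandana and was at least 73.3-fold lower (adjusted p = 0.00397). LOC_Os04g21130 fell by 5.45 (SE 0.81, adjusted p = 0.00158) and was above background on 1 of 3 drought arrays, so the size of this fall is not measured. Of the loci called higher, 246 were not well above background on any drought array. Without any 1 of the 6 Vandana arrays, between 1281 and 2291 loci were higher and between 1819 and 2694 lower, and without drought replicate 2 of the bred line, 5526 were higher. Within this cultivar slide and drought cannot be told apart. The slide of its drought arrays also held the well-watered arrays of the bred line, so an effect of that slide alone would move the responses of Vandana and the bred line in opposite directions, and they correlated at 0.80.

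In Way Rarem, 4572 loci were higher and 5030 lower under drought (3 against 3 arrays), 4305 and 4466 of them by at least 1 log2 unit. LOC_Os03g42520 rose by 8.61 (SE 1.21, adjusted p = 3.62e-04) and LOC_Os11g18570 by 8.37 (SE 1.23, adjusted p = 4.73e-04). Both also rose in the bred line, by 4.77 and 6.39, and in Vandana, by 4.39 and 4.73. Only 1 of 3 well-watered arrays of Way Rarem, 1 of 2 of the bred line and none of Vandana measured LOC_Os11g18570 above background. The sizes of its rises are therefore not measured. At LOC_Os03g42520, 2 of 3 well-watered Way Rarem arrays were above background, and replicates 1 to 3 stood at -1.29, -4.54 and -7.36. The size of its rise in Way Rarem is therefore not measured either. LOC_Os04g21130 fell by 8.44 (SE 0.81, adjusted p = 2.67e-05), from 6.03 ± 0.60 to -2.41 ± 1.18 (mean ± SD, n = 3). LOC_Os06g46160 was not well above background on any drought array and was at least 116-fold lower (adjusted p = 4.54e-05). Well-watered replicate 1 showed raised signal at control probes that have no rice target, with an ERCC median of 47.5 intensity units. Drought replicate 1 had the next highest, 3.63, close to the 2.92 of well-watered replicate 2. Without both number 1 arrays, 2906 loci were higher and 2164 lower. Without well-watered replicate 2 or 3, 2648 or 2618 were higher and 2606 or 2468 lower. Without drought replicate 3, 2912 were higher and 3306 lower, and without drought replicate 1, 3023 were lower. Slide and drought cannot be told apart in this cultivar either.

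The 3 responses overlapped. A set of 1543 loci was higher in all 3 cultivars and 1813 were lower in all 3, where independent lists of these lengths would share 58.2 and 75.1. The cultivars share no control arrays, but they share slides. Way Rarem drought replicates 2 and 3 lay on the slide of the bred line's drought arrays. Vandana well-watered replicates 1 and 3 lay on the slide of the well-watered Way Rarem arrays. The well-watered arrays of the bred line lay with drought arrays of Vandana, which would act the other way. A part of slide in the overlap was not tested. Median changes of the shared risen loci were 2.03 in the bred line, 1.77 in Vandana and 2.07 in Way Rarem, and those of the shared fallen loci were -1.71, -1.55 and -1.54. Across all tested loci, the log2 changes correlated at 0.80 between the bred line and Vandana, 0.72 between the bred line and Way Rarem and 0.65 between Vandana and Way Rarem. These are correlations across loci, which are not independent replicates. Calls in opposite directions numbered from 3 loci, higher in the bred line and lower in Vandana, to 43, higher in the bred line and lower in Way Rarem. The shared counts were 67 and 93 without well-watered replicate 1 of the bred line and 3049 and 3649 without drought replicate 2 of the bred line.

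The share of calls that were higher depended on the scaling and the background correction. With the 75th percentile, 50.1% of calls were higher in the bred line, 46.0% in Vandana and 47.6% in Way Rarem, and the median change over all loci was 0.15, 0.16 and -0.03 log2 units. With the array median the shares were 19.8%, 19.7% and 42.2%, and the median changes were -0.54, -0.38 and -0.35. Scaling to the E1A transcripts, chosen after seeing the data, gave median changes of -1.38, -0.22 and -0.87. It gave 109 higher and 5197 lower loci in the bred line, 73 and 61 in Vandana, and 545 and 1804 in Way Rarem. Normexp background correction used the median signal, since the files lack the mean signal planned for it. It moved the balance the other way in the bred line, with 15594 higher and 6708 lower, and in Way Rarem, with 16105 and 6873. In Vandana it gave 2072 and 3879.

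A drought index placed each array between the treatments. It is the mean over loci called higher in both other cultivars minus the mean over loci called lower in both, relative to the well-watered mean of the array's own cultivar. The 3 Vandana drought arrays lay at 3.03, 2.96 and 2.98 log2 units and the 3 Way Rarem drought arrays at 3.40, 3.17 and 3.75. The drought arrays of the bred line were less alike, at 4.47, 2.27 and 4.55 for replicates 1 to 3. All 8 well-watered arrays lay between -0.28 and 0.28.

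**Figure D1:**
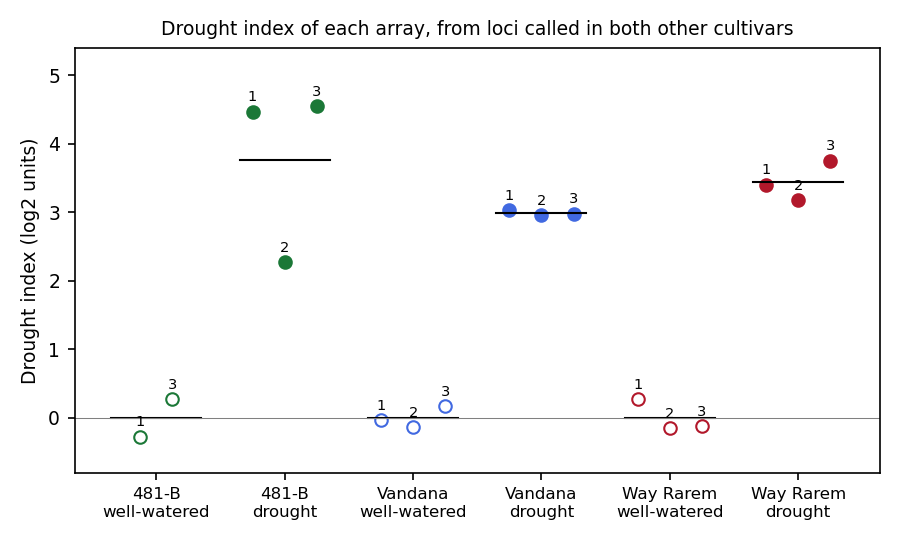
Drought index in log2 units (vertical axis) of each array, by cultivar and treatment (horizontal axis). Points are arrays with their replicate number, open for well-watered and filled for drought, and black lines are group means. Drought replicate 2 of the bred line, at 2.27, lies below the other drought arrays.

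Whether the cultivars responded differently was tested as the difference between their drought changes. Between the bred line and Vandana, 1 locus passed (limma, adjusted p under 0.05), and at an unadjusted p under 0.05 the value was higher in the bred line at 680 loci and lower at 807. That locus, LOC_Os03g11220 on chromosome 3, changed by -1.0 under drought in the bred line (adjusted p = 0.021), whereas it rose by 2.03 in Vandana (adjusted p = 5.76e-04) and 1.37 in Way Rarem (adjusted p = 0.00162). The difference from Vandana was -3.02 (SE 0.37, adjusted p = 0.0277). In well-watered leaves its mean was 3.81 in the bred line (2 arrays) and 1.55 ± 0.30 in Vandana (mean ± SD, n = 3). The difference passed the test in 9 of 30 alternatives.

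Between the bred line and Way Rarem, 22 loci differed in their drought change, 17 with the higher value in the bred line. The largest, LOC_Os07g10940 with 7.21 (SE 0.77, adjusted p = 0.00554) and LOC_Os02g11960 with 6.53 (SE 0.87, adjusted p = 0.0218), were above background on all 3 well-watered and no drought Way Rarem arrays, and changed there by -4.04 and -4.29. Of the 5 arrays of the bred line, 1 and 0 measured them above background, and 3.17 and 2.24 of these differences are changes of the bred line at or below background. What was measured is a fall in Way Rarem, and neither the size nor the rank of these differences is measured. In the other direction, LOC_Os05g39770 rose by 5.56 in Way Rarem, and the bred line changed by 0.82 (adjusted p = 0.298; difference -4.74, SE 0.77, adjusted p = 0.0396). LOC_Os02g33070 rose by 3.79 in Way Rarem and its value in the bred line was -0.53 (difference -4.32, SE 0.57, adjusted p = 0.0218). Without Way Rarem drought replicate 2 the count was 1077, and without well-watered replicate 3 of the bred line it was 0.

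Vandana and Way Rarem differed in their drought change at 79 loci, 52 with the higher value in Vandana. LOC_Os08g39410 (6.73, SE 1.24, adjusted p = 0.0428) and LOC_Os06g09780 (6.06, SE 0.79, adjusted p = 0.0121) changed in Way Rarem by -5.51 and -3.91, where 1 of 3 drought arrays measured them above background. No Vandana array did, and 1.23 and 2.16 of these differences are changes of Vandana below background, so their size and rank are not measured. LOC_Os05g15530 rose by 5.18 in Way Rarem, against -1.47 in Vandana (adjusted p = 0.213; difference -6.66, SE 1.22, adjusted p = 0.0428). Of the well-watered Way Rarem arrays, 2 of 3 measured it above background. LOC_Os04g20749 rose in Way Rarem to 0.49 ± 0.71 (mean ± SD, n = 3), by 6.68 from a level that only 1 of 3 well-watered arrays measured above background, and was not well above background on any Vandana array (difference -5.39, SE 0.88, adjusted p = 0.0292), so the sizes of this rise and difference are not measured either. With slide as a fixed block, 295 loci passed, which under drought rests on 1 Way Rarem array, drought replicate 1. Leaving out Way Rarem drought replicate 2 gave 1660 loci, and leaving out Vandana well-watered replicate 1 gave 11.

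Few loci passed the test between the bred line and Vandana, and their number depended on the arrays, the fit and the scaling. With 1 probe per locus, such differences can be of expression or of sequence under the probe. In well-watered leaves 5 loci were higher and 1 lower than in Vandana (limma, adjusted p under 0.05), with 1700 and 3373 at an unadjusted p under 0.05. Leaving out 1 array gave 1 to 71 loci in well-watered leaves, and fitting only the groups compared gave 1903. Quantile normalization and the array median each gave 16, and E1A scaling gave 18548 higher and 12 lower. Under drought 2 were higher and 0 lower, with 1782 and 1823 at an unadjusted p under 0.05. LOC_Os07g03930, on chromosome 7, passed under both treatments. It was not well above background on any Vandana array and was at least 103-fold higher in the well-watered bred line (adjusted p = 9.00e-04) and at least 14.3-fold higher under drought (adjusted p = 0.0371, passed in 14 of 30 alternatives). In the bred line it stood at 1.67 ± 1.09 (mean ± SD, n = 2) when watered and 0.22 ± 1.46 (n = 3) under drought, against 2.51 ± 0.37 and 0.67 ± 1.02 in Way Rarem (n = 3), from which the test did not separate it (adjusted p = 0.812 and 0.925). LOC_Os06g32355, on chromosome 6, was at least 9.62-fold higher in the well-watered bred line than in Vandana (adjusted p = 0.0255) and was not well above background on any Way Rarem array either. LOC_Os11g14450 was not well above background on arrays of the bred line and was at least 7.85-fold lower in the well-watered line (adjusted p = 0.0247), measured on 2 of 3 well-watered Vandana arrays. The second locus called under drought, LOC_Os03g11734, was chosen after its values were seen. It was at least 2.68-fold higher in the bred line than in Vandana, where no drought array and all 3 well-watered arrays measured it above background (adjusted p = 0.0371). With normexp background correction its difference was -0.075 (adjusted p = 0.863). With slide as a fixed block 1 locus was called under drought, with Way Rarem drought replicate 1 as the only link between the slides. Without drought replicate 2 of the bred line the count under drought was 447.

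**Figure D2:**
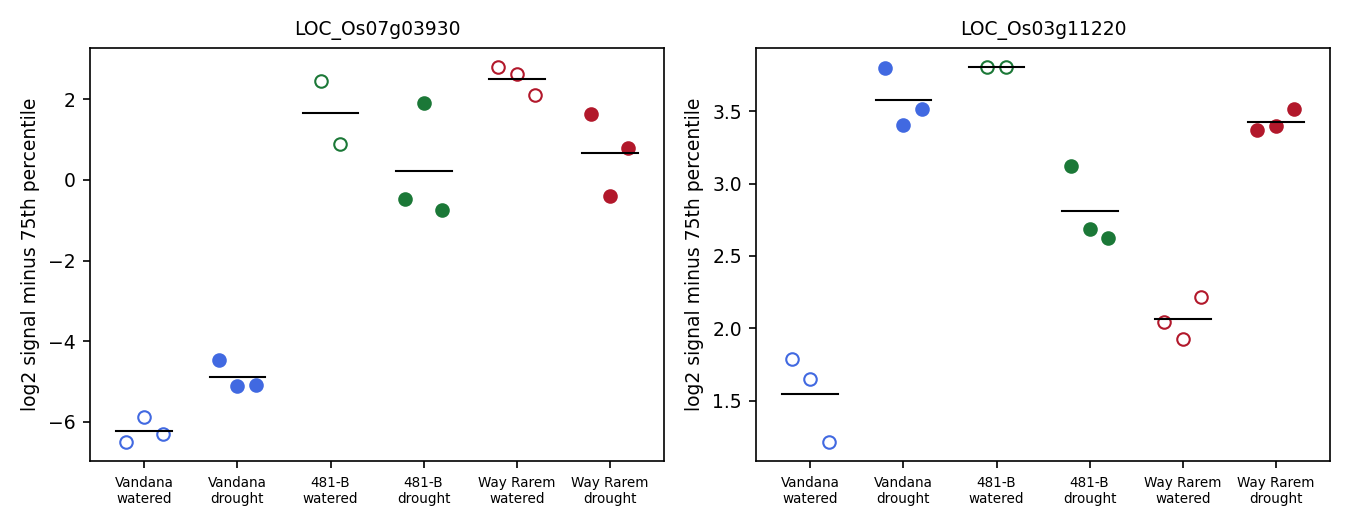
Signal of 2 loci on each array, as log2 signal minus the 75th percentile of the array (vertical axes), by cultivar and treatment (horizontal axes). Points are arrays, open for well-watered and filled for drought, and black lines are group means. LOC_Os07g03930 is at the level of Way Rarem in the bred line and below background in Vandana, and LOC_Os03g11220 fell under drought in the bred line and rose in both other cultivars.

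Signal differed widely between the 2 parents. Each locus has 1 probe, so a difference between cultivars, here and below, can be one of expression or of sequence under the probe. In well-watered leaves 1560 loci were higher in Vandana and 1655 higher in Way Rarem, and under drought the counts were 794 and 925. Leaving out 1 array gave totals of 1088 to 5448 in well-watered leaves and 675 to 3997 under drought. LOC_Os01g58035 was higher in Vandana by 13.71 log2 units (SE 0.48, adjusted p = 1.63e-09) and LOC_Os02g24636 by 13.55 (SE 0.61, adjusted p = 1.85e-08). The arrays of the bred line were at the Vandana side, with 12.51 and 12.38 over Way Rarem. The probes of both loci gave nearly the same signal, with well-watered means of 9.97 and 9.95 in Vandana and 8.77 and 8.79 in the bred line. Whether they bind the same transcript was not tested, so they may not be separate evidence. LOC_Os01g56830 and LOC_Os11g12350 were not well above background in Vandana or the bred line. In well-watered leaves they were at least 345-fold and 321-fold lower in Vandana than in Way Rarem (adjusted p = 0.00419 and 2.99e-04), and at least 869-fold and 808-fold lower in the bred line (adjusted p = 0.00551 and 3.05e-04). Under drought only 1 and 2 of 3 Way Rarem arrays measured them above background. Against Way Rarem, the bred line was higher at 446 loci and lower at 897 in well-watered leaves, and higher at 311 and lower at 260 under drought. The total under drought ran from 286 to 2062 when 1 array was left out. The balance in well-watered leaves depended on the scaling. Higher and lower loci numbered 456 and 280 with quantile normalization and 732 and 497 with the array median, and between Vandana and Way Rarem 1373 and 922 and 1303 and 844. With E1A scaling 224 and 9672 loci were higher and lower in Vandana than in Way Rarem in well-watered leaves and 46 and 519 under drought. With slide as a fixed block the counts between the parents were 2993 in well-watered leaves and, resting on 1 Way Rarem array (drought replicate 1), 901 under drought. The count was 361 between the bred line and Way Rarem under drought. Within a single slide these counts were 6291 (2 against 3 arrays), 370 (3 against 1) and 48 (3 against 2). The 370 rest on 1 Way Rarem array, drought replicate 1, with the spread taken from the Vandana arrays alone.

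At loci that separate the parents, the bred line was placed between them. The parents differed at 528 loci by at least 1 log2 unit in the same direction under both treatments, 318 higher in Vandana and 210 higher in Way Rarem. On a scale where Vandana is 0 and Way Rarem is 1, the median position of the bred line was 0.25. It lay nearer Way Rarem at 136 of these loci, or 25.8% (exact binomial 95% confidence interval 22.1 to 29.7, across loci). Where the parents differed by at least 2 log2 units under both treatments, it lay nearer Way Rarem at 21 of 273 loci, or 7.69%, with a median position of 0.11. At the other 255 loci the median position was 0.45. These values depended on the scaling. With quantile normalization, the array median and E1A scaling the shares nearer Way Rarem were 20.2%, 7.62% and 50.1%. With loci chosen anew under each scaling, the median positions were 0.12, 0.032 and 0.47 at the larger parental differences. At the smaller ones they were 0.37, 0.066 and 0.91, over 219, 32 and 24 loci. At the same 273 loci as above they were 0.11, 0.044 and -0.20. At the same 255 loci they were 0.45, 0.33 and 0.62, although with E1A scaling the difference between the parents changed sign at 80 of them. The share nearer Way Rarem by chromosome ran from 14.6% on chromosome 9 (7 of 48) to 40.6% on chromosome 10 (13 of 32), and chromosome 12 held 9 of 32. No chromosome differed from the rest (Fisher's exact test over 12 chromosomes, lowest p = 0.0595, adjusted p = 0.415). Without both Way Rarem number 1 arrays the share was 10.1%. Leaving out single arrays gave 12.9%, without Vandana well-watered replicate 3, to 41.6%, without Way Rarem drought replicate 3.

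**Figure D3:**
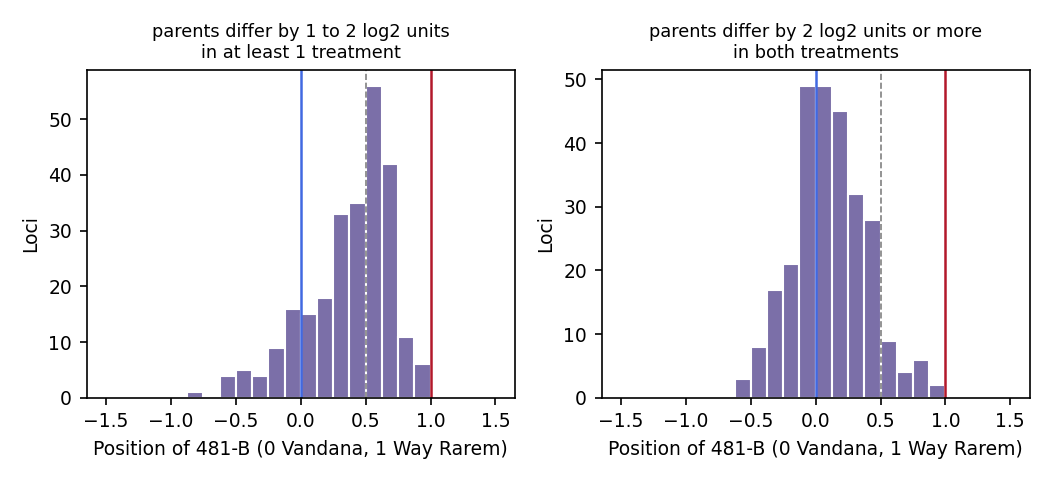
Number of loci (vertical axes) by the position of the bred line between Vandana, at 0, and Way Rarem, at 1 (horizontal axes), for loci where the parents differed by 2 log2 units or more under both treatments (right) and the other parental-difference loci (left). Solid lines mark the parents and the dashed line the midpoint at 0.5. The right panel centres near Vandana, with a median of 0.11, and the left panel has a median of 0.45.

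Presence above background needs no scaling between arrays, but depends on their brightness and on the sequence under the probe. On average 75.7% of probes were above background on well-watered and 60.7% on drought Way Rarem arrays, against 57.3% and 47.7% in Vandana. By this measure 86 loci were above background on all 6 Way Rarem arrays and on no Vandana array. Of these, 35 were above background on no array of the bred line and 2 on all 5. In the other direction 2 loci were above background on all Vandana arrays and no Way Rarem array. Without Way Rarem well-watered replicate 1 these were 26 loci, of which 21 were above background on all 5 arrays of the bred line.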

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

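Tests on the split counts and on added dim-probe signal were set before their results were seen, and the test on local background after. No group has more than 3 arrays, so Dixon's test for outliers was not run within groups.

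Differences between the drought responses of 2 cultivars passed the test of the difference itself at 1 locus for the bred line against Vandana, 22 for the bred line against Way Rarem and 79 for Vandana against Way Rarem. The locus that passed for the bred line minus Vandana was LOC_Os03g11220 (-3.02). The largest estimated differences for the bred line minus Way Rarem were at LOC_Os07g10940 (7.21), LOC_Os02g11960 (6.53), LOC_Os05g39770 (-4.74) and LOC_Os02g33070 (-4.32). For Vandana minus Way Rarem they were at LOC_Os08g39410 (6.73), LOC_Os06g09780 (6.06), LOC_Os05g15530 (-6.66) and LOC_Os04g20749 (-5.39). Neither sizes nor ranks are measured at LOC_Os07g10940, LOC_Os02g11960, LOC_Os08g39410, LOC_Os06g09780 and LOC_Os04g20749. At least 1 of the 2 cultivars was there at or below background under both treatments on nearly all arrays. For Vandana against Way Rarem, cultivar labels were exchanged within treatments, and 7 of the 100 splits drawn, the real one included, gave at least 79 loci. The highest other split gave 6026. An exchange in 1 treatment alone turns the contrast into a difference between the cultivars, so high counts can come from cultivar itself. These splits therefore cannot decide whether chance gave the 79 loci, and chance is not excluded.

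The 6 arrays of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For drought in Vandana, the real split gave 3468 higher and 4075 lower loci and no other split over 1, so 1 of the 10 splits reached each count. For drought in Way Rarem, 4572 and 5030 stood against 3403 in the highest other split, which sets drought replicates 1 and 3 with well-watered replicate 1 against the rest. Vandana against Way Rarem gave 3215 loci in well-watered leaves, with 0 in the highest other split, and 1719 under drought, with 59. Under drought, the bred line against Vandana gave 2 loci, and 2 of the 10 splits reached that, the highest other giving 97. For the bred line against Way Rarem under drought, 3 of the 10 splits reached 571, the highest other giving 6534. That split sets replicates 1 and 3 of the bred line with Way Rarem replicate 3. Their 75th percentiles were 35.7, 35.7 and 35.2 intensity units. The others, replicate 2 of the bred line and Way Rarem replicates 1 and 2, had 155, 96.6 and 141. The split thus separates dimmer from brighter arrays. It also separates drought indices of 4.47, 4.55 and 3.75 from 2.27, 3.40 and 3.17. Which of these the calls follow cannot be told. The fit within 1 slide gave 48.

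Control probes without a rice target, outside the main measurement, were bright on Way Rarem well-watered replicate 1. The 12 ERCC probes had a median signal of 47.5 there, against 1.46 to 3.63 on the other arrays, of which Way Rarem drought replicate 1 was the highest. Local background around the spots argues against itself as the source, as it exceeded that of the other well-watered Way Rarem arrays by only 2.5 intensity units. Dim rice probes shared the raised signal, as signal added to all dim probes would give. The 16510 rice probes that were dim on both other arrays had a median of 38.0 on this one, against 2.14 and 1.75. The 308 negative control spots did not share it. Their median signal before background subtraction was 26, against 27 and 26 on well-watered replicates 2 and 3, which argues against signal added to every dim spot. What added the signal stays open, and no biological explanation was tested, since these probes have no rice target.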

How the results depend on the processing

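The alternatives named normexp, E1A scaling, leaving out both Way Rarem number 1 arrays, the filter on both groups, fits within a slide and the parental difference of at least 4 were chosen after seeing the data. Values that stayed within 1.5 times their reported count, or within the spread between arrays, are left out below. Except where the way an alternative is built shows it, the cause was not tested.

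For the named loci, direction and call held in 348 of 353 alternatives of drought responses, 238 of 240 of differences from Way Rarem in well-watered leaves, 146 of 268 of differences between drought responses and 85 of 147 of differences between the bred line and Vandana. All others kept their direction and lost the call, except LOC_Os03g11734 under drought, which went to -0.075 with normexp (adjusted p = 0.863; range over its alternatives 2.48e-05 to 0.863).

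No filter on dim probes gave 2657 higher and 2343 lower in the bred line, 1783 higher and 2166 lower in Vandana, 3240 lower in Way Rarem and 752 higher and 822 lower in all 3 under drought. The difference between drought responses passed at 0 (bred line against Vandana), 1 (bred line against Way Rarem) and 14 (Vandana against Way Rarem) loci. Between cultivars in well-watered leaves the counts were 1 (bred line against Vandana) and 1740 (Vandana against Way Rarem) loci. Between cultivars under drought the counts were 0 (bred line against Vandana), 355 (bred line against Way Rarem) and 823 (Vandana against Way Rarem) loci. The correlations were 0.70 (bred line and Way Rarem). A share of 13.1% lay nearer Way Rarem.

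A filter to loci well above background on all 17 arrays gave 7 (bred line against Way Rarem) loci with a difference between drought responses. In well-watered leaves, cultivars differed at 1 (bred line against Vandana), 277 (bred line against Way Rarem) and 1888 (Vandana against Way Rarem) loci. Under drought, cultivars differed at 0 (bred line against Vandana) and 173 (bred line against Way Rarem) loci. The correlations were 0.87 (bred line and Vandana), 0.85 (bred line and Way Rarem) and 0.78 (Vandana and Way Rarem). Nearer Way Rarem lay 41.8%.

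Quantile normalization gave 2403 higher in the bred line under drought. At 0 (bred line against Vandana) and 14 (bred line against Way Rarem) loci the drought responses differed. Counts between cultivars in well-watered leaves were 16 (bred line against Vandana) and 736 (bred line against Way Rarem) loci. Counts between cultivars under drought were 17 (bred line against Vandana) loci. The share nearer Way Rarem was 20.2%.

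The array median gave 1010 higher in the bred line, 609 higher and 2481 lower in Vandana, 2305 higher and 3153 lower in Way Rarem and 242 higher and 947 lower in all 3 under drought. Drought responses differed at 0 (bred line against Vandana) loci. Cultivars differed in well-watered leaves at 16 (bred line against Vandana) loci. Cultivars differed under drought at 1 (bred line against Vandana) and 768 (Vandana against Way Rarem) loci. A share of 7.62% lay nearer Way Rarem.

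The deposited value table gave 2408 higher in the bred line under drought. The difference between drought responses passed at 0 (bred line against Vandana) and 14 (bred line against Way Rarem) loci. Between cultivars in well-watered leaves the counts were 16 (bred line against Vandana) and 735 (bred line against Way Rarem) loci. Between cultivars under drought the counts were 17 (bred line against Vandana) loci. Nearer Way Rarem lay 20.4%.

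A trended robust prior gave 2 (bred line against Vandana) loci between cultivars in well-watered leaves. Under drought, cultivars differed at 1 (bred line against Vandana) loci.

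Limma array weights gave 13245 higher and 10982 lower in the bred line, 9384 higher and 8755 lower in Vandana, 11819 higher and 10330 lower in Way Rarem and 5639 higher and 5430 lower in all 3 under drought. At 10531 (bred line against Vandana), 9813 (bred line against Way Rarem) and 9720 (Vandana against Way Rarem) loci the drought responses differed. Counts between cultivars in well-watered leaves were 10387 (bred line against Vandana), 6709 (bred line against Way Rarem) and 14866 (Vandana against Way Rarem) loci. Counts between cultivars under drought were 8241 (bred line against Vandana), 11944 (bred line against Way Rarem) and 13605 (Vandana against Way Rarem) loci. The correlations were 0.73 (bred line and Vandana), 0.66 (bred line and Way Rarem) and 0.53 (Vandana and Way Rarem). A share of 34.6% lay nearer Way Rarem. These counts are doubtful, since weights from 0.089 to 4.48 were estimated within groups of 2 or 3 arrays and then taken as known.

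Slide as a random block gave 43 (bred line against Way Rarem) loci with a difference between drought responses. Cultivars differed in well-watered leaves at 23 (bred line against Vandana) loci. Cultivars differed under drought at 9 (bred line against Vandana) loci.

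Slide as a fixed block gave 87 higher and 112 lower in the bred line under drought. The difference between drought responses passed at 295 (Vandana against Way Rarem) loci. Between cultivars under drought the counts were 1 (bred line against Vandana), 361 (bred line against Way Rarem) and 901 (Vandana against Way Rarem) loci. All of these fixed-block counts but the 361 rest on Way Rarem drought replicate 1, the only array of its group on its slide.

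Fitting only the groups of the comparison gave 309 higher and 303 lower in the bred line, 7030 higher in Vandana, 2236 higher and 2696 lower in Way Rarem and 126 higher and 158 lower in all 3 under drought. Loci that differed in drought response numbered 0 (bred line against Vandana), 0 (bred line against Way Rarem) and 40 (Vandana against Way Rarem). In well-watered leaves, cultivars differed at 1903 (bred line against Vandana) and 5691 (Vandana against Way Rarem) loci. Under drought, cultivars differed at 107 (bred line against Way Rarem) and 310 (Vandana against Way Rarem) loci. A share of 8.67% lay nearer Way Rarem.

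A parental difference of at least 2 gave a share nearer Way Rarem of 7.69%.

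A parental difference of at least 4 gave a share nearer Way Rarem of 7.69%.

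Normexp on the median signal gave 15594 higher and 6708 lower in the bred line, 2072 higher in Vandana, 16105 higher in Way Rarem and 3004 lower in all 3 under drought. The difference between drought responses passed at 57 (bred line against Way Rarem) and 331 (Vandana against Way Rarem) loci. Between cultivars in well-watered leaves the counts were 90 (bred line against Vandana) and 15003 (Vandana against Way Rarem) loci. Between cultivars under drought the counts were 0 (bred line against Vandana), 126 (bred line against Way Rarem) and 278 (Vandana against Way Rarem) loci. The correlations were 0.91 (bred line and Vandana), 0.88 (bred line and Way Rarem) and 0.82 (Vandana and Way Rarem). A share of 12.2% lay nearer Way Rarem.

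E1A scaling gave 109 higher in the bred line, 73 higher and 61 lower in Vandana, 545 higher and 1804 lower in Way Rarem and 21 higher and 52 lower in all 3 under drought. Loci that differed in drought response numbered 0 (bred line against Vandana), 2 (bred line against Way Rarem) and 26 (Vandana against Way Rarem). In well-watered leaves, cultivars differed at 18560 (bred line against Vandana), 421 (bred line against Way Rarem) and 9896 (Vandana against Way Rarem) loci. Under drought, cultivars differed at 0 (bred line against Vandana), 109 (bred line against Way Rarem) and 565 (Vandana against Way Rarem) loci. Nearer Way Rarem lay 50.1%.

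Leaving out both Way Rarem number 1 arrays gave 2906 higher and 2164 lower in Way Rarem and 958 lower in all 3 under drought. At 0 (bred line against Vandana), 1 (bred line against Way Rarem) and 9 (Vandana against Way Rarem) loci the drought responses differed. Counts between cultivars in well-watered leaves were 2041 (Vandana against Way Rarem) loci. Counts between cultivars under drought were 0 (bred line against Vandana) and 709 (Vandana against Way Rarem) loci. The correlations were 0.76 (bred line and Way Rarem) and 0.69 (Vandana and Way Rarem). The share nearer Way Rarem was 10.1%.

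Fits within a slide gave 6291 (Vandana against Way Rarem) loci between cultivars in well-watered leaves. Cultivars differed under drought at 48 (bred line against Way Rarem) and 370 (Vandana against Way Rarem) loci.

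The replicate block gave 7208 higher in the bred line under drought. The difference between drought responses passed at 0 (bred line against Vandana) and 35 (bred line against Way Rarem) loci. Between cultivars in well-watered leaves the counts were 15 (bred line against Vandana) loci. Between cultivars under drought the counts were 0 (bred line against Vandana) loci. Nearer Way Rarem lay 31.1%. The replicate block does not rest on pairs: deviations from the group means correlated over 0.1 between arrays of the same number in 4 of 8 cases, with r from -0.14 to 0.52, and 4 of 8 correlated best with their own number.

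Leaving out each of the 17 arrays in turn gave ranges of 90 to 8210 for the bred line higher, 123 to 7383 for the bred line lower, 1281 to 5526 for Vandana higher, 1819 to 5963 for Vandana lower, 2618 to 6649 for Way Rarem higher, 2468 to 6934 for Way Rarem lower, 67 to 3049 for all 3 cultivars higher and 93 to 3649 for all 3 cultivars lower. Between drought responses the ranges were 0 to 4 for the drought responses of the bred line against Vandana, 0 to 1077 for the drought responses of the bred line against Way Rarem and 11 to 1660 for the drought responses of Vandana against Way Rarem. Between cultivars they were 0 to 447 for the bred line against Vandana under drought, 1 to 71 for the bred line against Vandana in well-watered leaves, 286 to 2062 for the bred line against Way Rarem under drought, 405 to 1757 for the bred line against Way Rarem in well-watered leaves, 675 to 3997 for Vandana against Way Rarem under drought and 1088 to 5448 for Vandana against Way Rarem in well-watered leaves. They were 0.74 to 0.81 for the correlation of the bred line and Vandana, 0.64 to 0.73 for the correlation of the bred line and Way Rarem, 0.59 to 0.67 for the correlation of Vandana and Way Rarem and 12.9 to 41.6% for the share nearer Way Rarem. The arrays with the strongest effect were well-watered replicate 1 and drought replicate 2 of the bred line, for its counts and the shared counts, and Way Rarem drought replicate 2, for the differences between drought responses that include Way Rarem.

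Not run were normexp on the mean spot signal, a column that the scanner files lack, and the alternatives on several probes per gene, since each locus has 1 probe. Gene lists and anchor genes were not matched to probes. Signal over background limits dim loci, whose changes depend on the background level of the dimmer arrays.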

Other observations

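The tests on neighbouring loci, on chromosome shares, on slide, on exchanged arrays, both tests on scatter, those on scaling with loci chosen anew and that on linked segments among all parental-difference loci were chosen only after the result was seen.

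Loci that changed under drought in all 3 cultivars lay side by side on the chromosomes more often than permuted labels. Among tested loci in chromosome order, 173 neighbouring pairs were both lower in all 3 cultivars, against a mean of 103 when labels were permuted within chromosome and signal decile (permutation p = 1e-04, the smallest that 10000 permutations can give). The pairs both higher numbered 94, against a mean of 71.5 (permutation p = 0.004). Runs of 4 neighbouring loci were the longest. One such run rose, from LOC_Os11g26750 to LOC_Os11g26790 on chromosome 11, and 3 fell on chromosome 1, among them the run from LOC_Os01g66820 to LOC_Os01g66850. A hypothesis is that neighbouring loci share regulation or are copies of 1 gene, and probes that bind transcripts of both copies could give the same result. Probe sequences were not analysed here.

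By chromosome, the shared fallen loci were most frequent on chromosome 2, at 244 of 3625 tested loci (6.73%, Fisher's exact test against the rest, adjusted p = 0.00146 over 24 tests), and least on chromosome 8, at 88 of 2368 (3.72%, adjusted p = 0.00344). The shared risen loci were most frequent on chromosome 9, at 115 of 2000 (5.75%, adjusted p = 0.0221), and least on chromosome 2, at 132 of 3625 (3.64%, adjusted p = 0.0256). Fisher's test takes loci as independent, whereas the shared loci lay side by side, so these p-values may be too small. The shares were not matched for signal.

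Drought replicate 2 of the bred line showed a smaller drought shift than its group, at 50.4% of the mean of replicates 1 and 3 on the drought index. Loci near background do not account for this, since over loci well above background on all arrays the value was 46.1%. Neither does an effect common to its slide, which also held replicates 1 and 3. Other arrays of the slide reached at least 84.7% of the highest index of their group. The arrays with those highest indices lay on the same slide, so this value could not show an effect of slide. The brightness of the array stays open, since the first of these tests removes only dim loci. Its 75th percentile was 155 intensity units, against 35.7 on replicates 1 and 3. Way Rarem drought replicate 2, at 141, also had the lowest index of its group, 3.17. An exchange with a well-watered array would need a partner, and the highest well-watered index in the series was 0.28, against 2.27 on this array. The series holds no well-watered replicate 2 of the bred line, so an exchange with that plant could not be tested. RNA of the well-watered bred line mixed into the sample would move risen and fallen loci by equal fractions on the linear scale. The fractions were 20.4% and 62.9%, 42.5 percentage points apart, while loci that differed by under 0.25 log2 units between the other drought and the well-watered arrays shifted by 0.12, so an error of scaling does not make up the gap. On the log2 scale the fractions were 38.9% and 43.1%, so a milder water deficit in this plant may be a candidate explanation, as a hypothesis that no soil or plant water value here can test.

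At loci with smaller parental differences, the median position of each array of the bred line lay between 0.37 and 0.49, while single Vandana arrays lay between -0.27 and 0.21 and single Way Rarem arrays between 0.79 and 1.14. The scaling alone does not account for this, since at the same 255 loci the median was 0.45 with the 75th percentile and, in the order of quantile normalization, array median and E1A scaling, 0.45, 0.33 and 0.62. The 0.62 carries little weight, since with E1A scaling the difference between the parents changed sign at 80 of these loci. With loci chosen anew under each scaling the medians were 0.37, 0.066 and 0.91 over 219, 32 and 24 loci. Scaling and loci change together there, so whether scaling acts through the choice of loci stays open. Scatter around the level of Vandana stays open. In a first test the share nearer Way Rarem fell from 25.8% to 7.69% where the parents differed by at least 2 log2 units, below the interval of the whole set, which scatter would give. A second test, set after that result and after the positions were seen, asked whether the median at the smaller differences was near 0, and it was 0.45. Choosing loci on the same Vandana arrays could raise this value. With loci chosen without 1 Vandana array per treatment and those arrays as the zero point, the medians were 0.24, 0.29 and 0.34 over 78, 100 and 45 loci. On the same loci, with the arrays used for choosing as the zero point, they were 0.28, 0.41 and 0.27. On that scale the held-out Vandana arrays themselves had medians of -0.018, 0.18 and -0.12. Held-out arrays as the zero point lowered 2 of the 3 medians of the bred line and raised the other, so an effect of selection stays open. The change of loci alone also moved the medians. Without both Way Rarem number 1 arrays the median was 0.26 over 71 loci, so those arrays stay open as a part of it. A difference of genotype was not tested.

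Segments inherited from Way Rarem were taken as a hypothesis for the loci at which the bred line lies nearer that parent. Such segments would place these loci side by side, and 33 neighbouring pairs were found against a mean of 34.0 in 10000 permutations (permutation p = 0.633). Linked segments therefore do not account for most of the 136 loci. For the 21 loci with a parental difference of at least 2 log2 units, 3 neighbouring pairs stood against a mean of 1.47 (permutation p = 0.169), too few loci to decide.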
